A study of Mus musculus with 4 samples.

How the data were processed

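RNA from infarcted and non-infarcted left ventricle of wild-type and Neil3-/- C57BL/6 mice, as labelled, was sequenced on an Illumina HiSeq 2000 from total RNA, with 1 library for each of the 4 groups. The deposited read counts are uniquely assigned reads per gene, keyed by Entrez gene identifier, and only genes with at least 1 read are listed. The deposited RPKM values (reads scaled to gene length and library total) were checked against the counts and equal reads divided by the listed length and by the library's total of unique reads, with a largest relative error of 6.66e-16. The deposited coverage values, headed Coverage and given in percent, were taken as the share of the gene model's length covered by reads. The submitters' processing notes name genome build mm9. The aligner, the counting tool and the gene annotation are not given in the sources used here. Listed length differed between files for 22 genes.

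The files list 16286 and 16446 genes for wild-type non-infarcted and infarcted tissue and 16249 and 16510 genes for the libraries labelled knockout, 17550 genes in any library. A gene not listed in a library was taken to have 0 reads. The totals of unique reads were 14895578 and 17260754 in wild type and 14290921 and 18200698 in the libraries labelled knockout. At these depths, 1 read on a gene of 2 kb is 0.0275 to 0.0350 RPKM, and 3 reads are a scaled read number (RPM) of 0.165 to 0.210. Where a group had no read, a ratio is given only as a bound against a floor of 3 reads, per library. No symbol stood for more than 1 gene, and 46 genes without a symbol were kept in counts but not named. A RefSeq table for another mouse assembly was used only for chromosome and order of genes, and matched 99.5% of genes. No coordinates are given.

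For each gene the log2 ratio of (RPKM + 1) was computed between infarcted and non-infarcted tissue within each genotype, between libraries labelled knockout and wild type within each region, and as the difference of both infarct ratios. Genes at 1 RPKM or more in at least 1 library compared were kept, and genes at least 2-fold apart were counted in each direction. No test across genes was run and no p-values were computed, since each comparison is between single libraries. An additive model of genotype and region, which leaves 1 residual degree of freedom, was not fitted. For named genes, the ratio of RPKM is given with the exact Clopper-Pearson 95% interval of the read share of both libraries. Overlaps of counted genes are given beside the number that independent lists would share.

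Named genes followed a rule fixed before the data were examined. They are Neil3, the 10 genes with the highest and the 10 with the lowest ratio in each comparison among genes at 5 RPKM or more in at least 1 library compared, and up to 4 members with the largest ratio in each gene list. The infarct comparisons share 1 ranking, on the smaller ratio of both genotypes. Genes with provisional or small RNA names may be left to counts.

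The 30 gene lists, with 419 genes of which 410 were found, were fixed before the data were examined as well. They cover cardiomyocyte contractile, calcium handling and ion channel, cardiac stress and fetal, oxidative phosphorylation, fatty acid oxidation, and glycolysis and hypoxia genes. They also cover neutrophil, monocyte and macrophage, lymphocyte, inflammatory cytokine and chemokine, interferon response and antigen presentation genes. Further lists hold extracellular matrix, fibroblast and myofibroblast, matrix protease and inhibitor, cell cycle, base excision repair, p53 target, and DNA methylation and hydroxymethylation genes. The last lists hold endothelial, smooth muscle and pericyte, immediate early, heat shock, erythrocyte, atrial, adipocyte, skeletal muscle, mesothelial and epicardial, lung and airway, and sex-linked genes. The median log2 ratio of a list's compared members was set among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside their central 95% is said to stand apart, which describes these libraries and does not test the conditions.

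Neil3 coverage was compared with that of genes whose length and read number both lay within 0.3 log2 units of its own. Genes at least 1.5-fold apart in the same direction in both regions were placed in runs of 100 neighbouring expressed genes and compared with 2000 random sets matched on expression. Biological process terms in the deposited files with 15 to 150 compared genes were ranked by median and compared with 2000 random lists. The calls were tested on data simulated with counting noise only, with 50 genes set at each of 4 changes in each comparison. A simulated 4-fold increase was found for 100% of genes, a fall to 0.25-fold for 82% to 94%, a 2-fold increase for 12% to 20% and a fall to 0.5-fold for 8% to 16%, while 5 to 10 genes set without a change were counted. Of 200 simulated lists of randomly drawn genes without a change, 2% to 5% stood apart. Differences between mice or dissections, and genes that move together, were not simulated. The simulated error is therefore no measure of the error of the counts and lists below.

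The alternatives were a pseudocount of 0.1 RPKM, no filter or a filter at 5 RPKM, median-ratio and TMM scaling, leaving out the 20 highest genes, scaled counts (CPM) with 0.5 reads added, thresholds of 1.5-fold and 4-fold, the mean of list members and random lists matched in 5 bins. Leaving out ribosomal and small noncoding RNA genes, or chromosome 1, was added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.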

Results

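The series measured gene expression by Illumina RNA sequencing in the left ventricle of 8-week-old C57BL/6 mice, wild type or labelled Neil3-/-, 3 days after an induced myocardial infarction. Infarcted and non-infarcted tissue was sequenced for each genotype, giving 4 libraries with 1 library per group. The labels do not say whether a library came from 1 mouse or from a pool. The files held 14.9 M uniquely assigned reads for wild-type non-infarcted tissue, 17.3 M for wild-type infarcted tissue, 14.3 M for the non-infarcted library labelled knockout and 18.2 M for the infarcted library labelled knockout. No difference given here has a replicate check. Ratios are therefore descriptions of these libraries, and the exact 95% intervals in parentheses cover counting error only.

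Neil3 codes for a DNA glycosylase that removes oxidised bases in base excision repair, and it was examined first as a possible check of the genotype labels. Its read number was higher, not lower, in both libraries labelled knockout. Neil3 (Entrez 234258) was at 1.83 RPKM (1.41 to 2.35) in wild-type non-infarcted tissue and 12 RPKM (10.9 to 13.3) in the non-infarcted library labelled knockout, from 62 and 391 reads. In infarcted tissue it was at 3.95 RPKM (3.36 to 4.63) in wild type and 18.5 RPKM (17.2 to 19.8) in the library labelled knockout, from 155 and 763 reads. Reads covered 63.4% and 73.4% of the Neil3 model in the wild-type libraries, and 62.9% and 71.5% in the libraries labelled knockout (non-infarcted and infarcted tissue in turn). Genes of like length and read number had a median coverage of 63.6% and 85.5% in the wild-type libraries and of 94.8% and 96.8% in the libraries labelled knockout. Neil3 coverage thus stood at or above that of 48.9% and 15.6% of such genes in wild type, but of 1.34% and 2.74% in the libraries labelled knockout. The labels do not name the deleted part of the gene, so the gene-level read number alone does not check the genotype, and every direction below is relative to libraries labelled knockout.

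**Figure D1:**
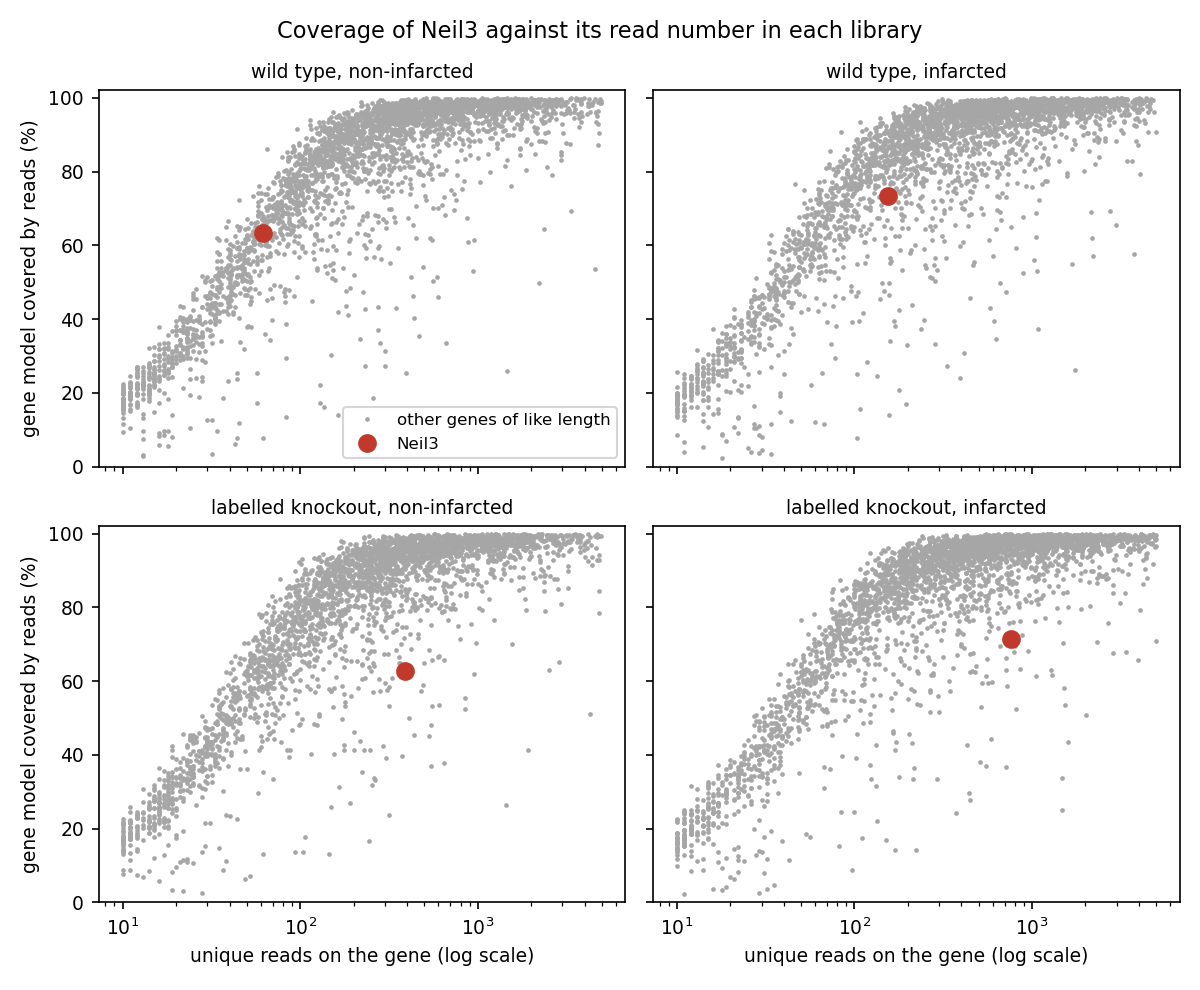
Percent of each gene model covered by reads against the number of unique reads on the gene (log scale), 1 panel per library, for genes of a length like that of Neil3 (grey) and Neil3 (red). Neil3 lies among genes of like read number at 62 reads in wild-type non-infarcted tissue and below most of them at 391 and 763 reads in the libraries labelled knockout.

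The first question was how infarcted differed from non-infarcted ventricle in each genotype. Genes of neutrophils, macrophages and inflammatory signalling were higher in infarcted tissue in both genotypes, and genes of contraction, calcium handling and mitochondrial energy supply were lower. Arg1, the arginase made by macrophages in wound repair, was at 118 RPKM in infarcted against 10.2 RPKM in non-infarcted wild-type tissue, an 11.5-fold difference (10.1 to 13.2). In the libraries labelled knockout it was 24.2-fold higher (20.5 to 28.9) in infarcted tissue. S100a8 and S100a9, which code for the subunits of calprotectin in neutrophils, were 8.44-fold (6.39 to 11.4) and 7.72-fold (6.01 to 10.05) higher in wild type, and 16.5-fold (11.5 to 24.5) and 9.62-fold (7.49 to 12.5) higher in the libraries labelled knockout. The gelatinase Mmp9 was 12.2-fold (9.56 to 15.9) and 12-fold (9.44 to 15.5) higher, and the decoy interleukin-1 receptor Il1r2 12.5-fold (8.41 to 19.4) and 23.0-fold (13.8 to 41.5) higher, in wild type and labelled knockout in turn. Chi3l3, a chitinase-like protein of macrophages, was 7.47-fold (6.54 to 8.57) and 10.2-fold (7.96 to 13.3) higher, and the neutrophil chemokine Cxcl3 31.6-fold (10.5 to 156) and 58.1-fold (15.8 to 484) higher. Crct1, Sh2d5 and AA467197 completed the 10 genes ranked highest.

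At the other end of the ranking, Myl7, the atrial regulatory myosin light chain, was at 49.0 RPKM in wild-type non-infarcted tissue and 0.290 RPKM in infarcted tissue, 169-fold lower (57.4 to 822). In the libraries labelled knockout it was 57.9-fold lower (15.6 to 486), from 10.6 RPKM to 0.183 RPKM. Myl4, the atrial essential light chain, was 28.3-fold lower (20.1 to 41.1) in wild type and 6.95-fold lower (4.88 to 10.2) in the libraries labelled knockout. Of ventricular genes, Kcnip2, a subunit of the transient outward potassium channel, was 7.79-fold (5.72 to 10.8) and 9.59-fold (7.06 to 13.3) lower. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, was 4.90-fold (4.64 to 5.18) and 6.58-fold (6.23 to 6.97) lower. Efnb3, Dhrs7c, Lrtm1, Scd4, Mylk4 and Mir208b, a microRNA gene within Myh7, were the other genes ranked lowest. Mir208b had 2 reads in wild-type infarcted tissue and none in the infarcted library labelled knockout.

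Counted at 2-fold on the log2(RPKM + 1) scale, 777 genes were higher and 450 lower in infarcted tissue among 12515 compared in wild type, and 1030 were higher and 762 lower among 12563 in the libraries labelled knockout. The added 1 RPKM understates the ratios of genes with low expression. The median log2 ratio of all compared genes was 0.21 and 0.24. Median-ratio scaling moved it by -0.19 and -0.20, and TMM scaling by -0.19 and -0.21, so the balance of the counts depends on scaling: genes higher in infarcted tissue made up 63.3% of the counted genes in wild type as deposited but 37.6% and 37.3% under these scalings, and 57.5% against 34.3% and 33.8% in the libraries labelled knockout. Gene lists are therefore set beside random lists of the same size and expression, which carry the same shift.

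The cardiomyocyte contractile list had a median log2 ratio of -1.15 in wild type and -1.46 in the libraries labelled knockout, at the 0.01 and 0 percentiles of random lists, with 9 and 13 of its 14 genes at least 2-fold lower in infarcted tissue. Tcap, the titin cap of the Z-disc, was 3.96-fold (3.78 to 4.15) and 5.80-fold (5.49 to 6.12) lower, and Myh6, the main myosin heavy chain of the adult mouse ventricle, 2.77-fold (2.75 to 2.79) and 4.52-fold (4.49 to 4.55) lower. Calcium handling and ion channel genes had medians of -1.25 and -1.57, both at percentile 0, with 8 of 12 genes at least 2-fold lower in each genotype. Pln, which codes for the calcium pump regulator phospholamban, was 3.25-fold lower (3.20 to 3.30) in wild type. The fatty acid oxidation list, at -1.26 and -1.65, had 15 of 16 genes at least 2-fold lower in each genotype, among them Fabp3, the fatty acid carrier of muscle (3.20-fold, 3.13 to 3.27, and 4.39-fold, 4.29 to 4.5). Oxidative phosphorylation genes were at -1.04 and -1.36, with 12 and 20 of 20 genes at least 2-fold lower, led by the muscle forms of cytochrome oxidase subunits Cox8b, Cox6a2 and Cox7a1. Both metabolic lists stood at percentile 0. These groups moved with the cardiomyocyte markers. Atrial genes were lower as well, at -3.15 and -1.69, with 4 and 3 of 5 genes at least 2-fold lower. The atrial list also differed between the non-infarcted libraries, at -1.47 in the library labelled knockout against wild type. The amount of atrial tissue in the sampled pieces therefore cannot be told apart from a response to infarction. Sln, the atrial regulator of the calcium pump, had no reads in either infarcted library and was at least 24.3-fold and 7.22-fold lower against a floor of 3 reads.

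The neutrophil list had a median of 2.39 in both genotypes, at percentile 100, with 8 of 9 compared genes at least 2-fold higher. Monocyte and macrophage genes were at 1.48 in wild type and 1.27 in the libraries labelled knockout, also at percentile 100, with 15 and 12 of 20 genes at least 2-fold higher. Itgam, an integrin subunit of myeloid cells, was 3.98-fold (3.71 to 4.28) and 4.41-fold (4.12 to 4.72) higher. Inflammatory cytokines and chemokines had medians of 1.52 and 2.12 at percentile 100, and 15 of 18 genes were at least 2-fold higher in each genotype. Il1b was 7.32-fold (5.20 to 10.6) and 9.81-fold (6.35 to 15.9) higher, Il6 7.57-fold (4.86 to 12.4) and 14.2-fold (8.59 to 25.1) higher, and the monocyte chemokine Ccl2 was 4.09-fold higher (3.67 to 4.57) in wild type. Antigen presentation genes were at 0.99 and 0.88, at percentiles 100 and 99.99, with 6 of 13 genes at least 2-fold higher in each, including the class II genes H2-Ab1 (2.69-fold and 2.42-fold) and H2-Aa (2.46-fold and 2.28-fold). Only 3 lymphocyte genes were expressed enough to compare in wild type, with a median of 1.02 (percentile 99.4), and 2 in the libraries labelled knockout, with a median of 0.95 that lay inside the central 95% of random lists.

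Matrix, protease and proliferation genes were higher in infarcted tissue too. The extracellular matrix list had medians of 0.72 and 0.90, at percentiles 99.96 and 99.99, with 4 and 9 of 23 genes at least 2-fold higher. Spp1, which codes for osteopontin, was 4.98-fold (4.81 to 5.16) and 6.67-fold (6.47 to 6.88) higher, the matricellular protein Thbs1 3.39-fold (3.27 to 3.51) and 4.48-fold (4.33 to 4.64), and fibronectin Fn1 2.65-fold (2.60 to 2.69) and 3.16-fold (3.11 to 3.20). Matrix proteases and inhibitors were at 1.47 and 1.53, at percentile 100, with 9 of 16 genes at least 2-fold higher and 1 at least 2-fold lower in each genotype. Timp1, a protease inhibitor, was 4.2-fold higher (4.0 to 4.42) in wild type, while its relative Timp4 was 6.61-fold lower (4.91 to 9.04) in the libraries labelled knockout. Fibroblast and myofibroblast genes were at 0.61 and 0.80, at percentiles 99.15 and 99.85, and Vim, an intermediate filament of mesenchymal cells, was 2.29-fold and 2.65-fold higher. In the cell cycle list, 30 of 30 genes lay above 0 in both genotypes under RPKM as deposited. Its medians were 0.91 and 1.19, at percentile 100, with 11 and 25 genes at least 2-fold higher, such as the mitotic kinase Plk1 (2.73-fold, 2.33 to 3.21, in wild type) and the mitotic cyclin Ccnb1 (2.96-fold, 2.55 to 3.46, in the libraries labelled knockout).

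Of the remaining lists, endothelial genes (0.61, percentile 99.17), erythrocyte genes (0.88, percentile 99.15), mesothelial and epicardial genes (0.73, percentile 97.71) and adipocyte genes (-0.86, percentile 2.01, a call lost under 3 settings) stood apart from random lists in wild type. Their medians in the libraries labelled knockout, 0.50, 0.63, 0.60 and -0.96, lay inside the central 95%. Immediate early genes (0.47 and 0.58) and DNA methylation genes (0.53 and 0.60) lay outside it in the libraries labelled knockout at percentiles 97.6 and 97.54, and both calls ended under several settings. Base excision repair (0.30 and 0.33), p53 target (0.38 and 0.26), interferon response (0.46 and 0.45) and heat shock genes (0.57 and 0.42) lay within random lists in both genotypes. The same held for skeletal muscle genes (0.13 and 0.28) and, with signs that turned in 1 or both genotypes under other scalings, for cardiac stress and fetal (0.48 and 0.07), glycolysis and hypoxia (0.35 and 0.04), smooth muscle and pericyte (0.08 and 0.12) and sex-linked genes (-0.23 and 0.01). Within them, the stress cytokine Gdf15 was 4.48-fold (3.70 to 5.45) and 2.57-fold (2.11 to 3.16) higher in infarcted tissue, and the lactate transporter Slc16a3 4.69-fold (4.19 to 5.26) and 4.24-fold (3.78 to 4.77) higher. No lung or airway gene reached 1 RPKM. In all, 18 and 15 of 29 lists stood apart, where lists of random genes would give 1.45. Members of a list tend to move together, so 2 libraries of 1 genotype could exceed that number too.

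**Figure D2:**
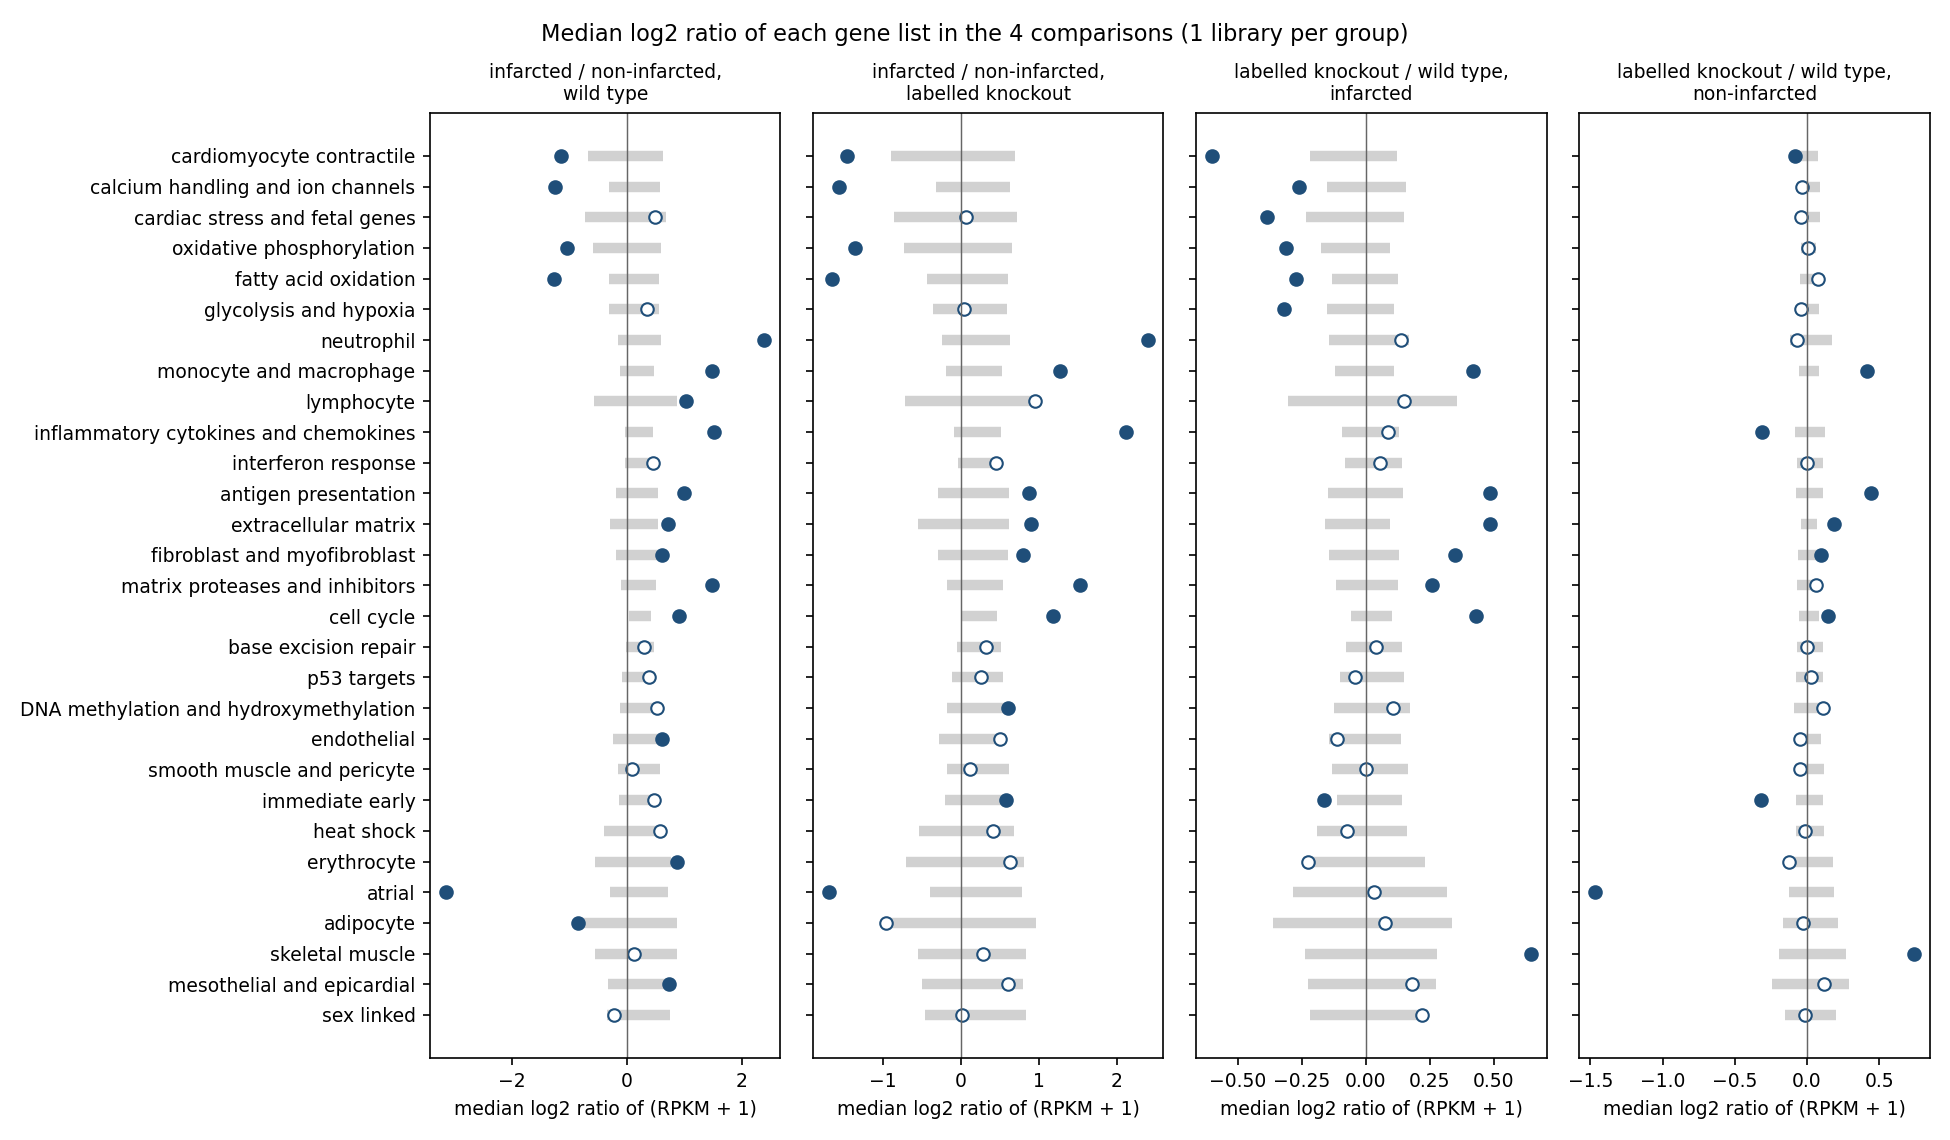
Median log2 ratio of (RPKM + 1) of each gene list, 1 panel per comparison. Circles are filled where the median lies outside the central 95% of 10000 matched random lists, drawn as grey bars, on axes that differ between panels. Cardiomyocyte contractile genes lie at -1.15 and -1.46 in infarcted against non-infarcted tissue, and at -0.60 in the infarcted library labelled knockout against wild type.

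The infarct responses of both genotypes were largely shared. Of 12362 genes compared in both, 771 and 1015 were at least 2-fold higher in infarcted tissue, and 619 of them were shared, where independent lists would share 63.3. Among the 441 and 750 lower genes, 409 were shared against 26.8 for independent lists, and 1 gene differed by 2-fold in opposite directions. Across genes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.932 and a Spearman correlation of 0.914.

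The second question was how the library labelled knockout differed from wild type in infarcted tissue. Ifi202b, an interferon-inducible gene of the p200 family, was at 22.8 RPKM in the library labelled knockout and 0.226 RPKM in wild type, 101-fold higher (48.7 to 252). Aim2, a cytosolic DNA sensor of the same family, was 2.66-fold higher (2.20 to 3.24). Myl1, a myosin light chain of fast skeletal muscle, was 2.62-fold higher (2.30 to 2.99), Neil3 4.67-fold higher (3.92 to 5.58), and BC002163 at least 15.5-fold higher, with no read in wild type. Nmrk2, a nicotinamide riboside kinase of muscle, was lower in the library labelled knockout, at 28.7 against 106 RPKM, 3.70-fold (3.45 to 3.98). Nppb, which codes for brain natriuretic peptide, a marker of ventricular wall stress, was 2.44-fold lower (2.38 to 2.51), at 524 against 1279 RPKM. Pcp4l1 (3.28-fold, 2.94 to 3.67), Wdfy1 (3.17-fold, 2.88 to 3.50), Chi3l3 (2.55-fold, 2.35 to 2.76) and the caveolin of muscle Cav3 (2.20-fold, 2.03 to 2.39) were lower as well, followed by Pirt, Dusp23 and 2310050B05Rik.

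At 2-fold, 31 genes were higher and 30 lower among 12464 compared, and 19 of the higher and 11 of the lower were ribosomal or small noncoding RNA genes. Of those, 4 (Rnu1a1, Rmrp, Rn7sk and Snord96a) were among the 10 ranked highest, beside 2210407C18Rik. Small noncoding RNA made up 0.00790% of reads in the infarcted library labelled knockout and 0.00600% in wild type, and ribosomal RNA 2.32% and 1.45%. Without both kinds of gene the counts were 13 and 19, an alternative chosen after seeing the data.

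Lists showed small shifts of many genes in this comparison, in which the cardiac stress list had 2 genes at least 2-fold lower and no other list had more than 1 gene at least 2-fold apart in a direction. Cardiomyocyte contractile genes were lower in the library labelled knockout, with 14 of 14 below 0 and a median of -0.60 (percentile 0). Myh6 was 1.79-fold lower (1.77 to 1.80) and the sarcomeric actinin Actn2 1.75-fold lower (1.72 to 1.78). Calcium handling genes were at -0.26 (percentile 0.15), oxidative phosphorylation genes at -0.31 (percentile 0.03) and fatty acid oxidation genes at -0.27 (percentile 0.02), the latter lists with every member below 0 as deposited. Glycolysis and hypoxia genes were at -0.32 (percentile 0.01), with the angiogenic factor Vegfa 1.63-fold lower (1.55 to 1.71). Cardiac stress and fetal genes were at -0.39 (percentile 0.10), with Myh7, the fetal myosin heavy chain, 2.12-fold lower (2.03 to 2.21) and Ankrd1 1.74-fold lower (1.72 to 1.76). Immediate early genes were at -0.16 (percentile 0.395), with Ier3 1.66-fold lower (1.55 to 1.78).

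In the same comparison, matrix and fibroblast genes were higher in the library labelled knockout. The extracellular matrix list had a median of 0.49 and fibroblast and myofibroblast genes one of 0.35, both at percentile 100. Fn1 was 1.67-fold (1.66 to 1.69), Spp1 1.66-fold (1.63 to 1.69) and the fibrillar collagen Col1a1 1.60-fold (1.59 to 1.62) higher, and the repair-associated Cthrc1 and Postn were 1.72-fold (1.61 to 1.84) and 1.52-fold (1.5 to 1.55) higher. Matrix proteases and inhibitors were at 0.26 (percentile 100), led by Mmp2 at 1.88-fold (1.74 to 2.02). Cell cycle genes were at 0.43 (percentile 100), with 29 of 30 above 0, and the proliferation marker Mki67 was 1.61-fold higher (1.56 to 1.67). Monocyte and macrophage genes were at 0.42 and antigen presentation genes at 0.48, both at percentile 100. The scavenger receptor Msr1 was 1.83-fold (1.73 to 1.94), H2-Aa 1.91-fold (1.78 to 2.05) and the invariant chain Cd74 1.66-fold (1.60 to 1.73) higher, against the lower Chi3l3. Skeletal muscle genes were at 0.65 (percentile 99.99), with 4 compared. Neutrophil (0.14), cytokine (0.09), lymphocyte (0.15), interferon response (0.06), p53 target (-0.04), DNA methylation (0.11), endothelial (-0.11), heat shock (-0.07), erythrocyte (-0.23), atrial (0.03), mesothelial (0.18) and sex-linked (0.22) medians lay within random lists, as did base excision repair (0.04) and, with signs that turned under other settings, adipocyte (0.07) and smooth muscle genes (0.00). Within these, Lcn2, a neutrophil lipocalin, was 1.71-fold lower (1.55 to 1.90) and Cnn1, a calponin of smooth muscle, 2.32-fold higher (1.99 to 2.72). In all, 14 of 29 lists stood apart, where lists of random genes would give 1.45, a number that does not cover differences between mice or dissections.

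**Figure D3:**
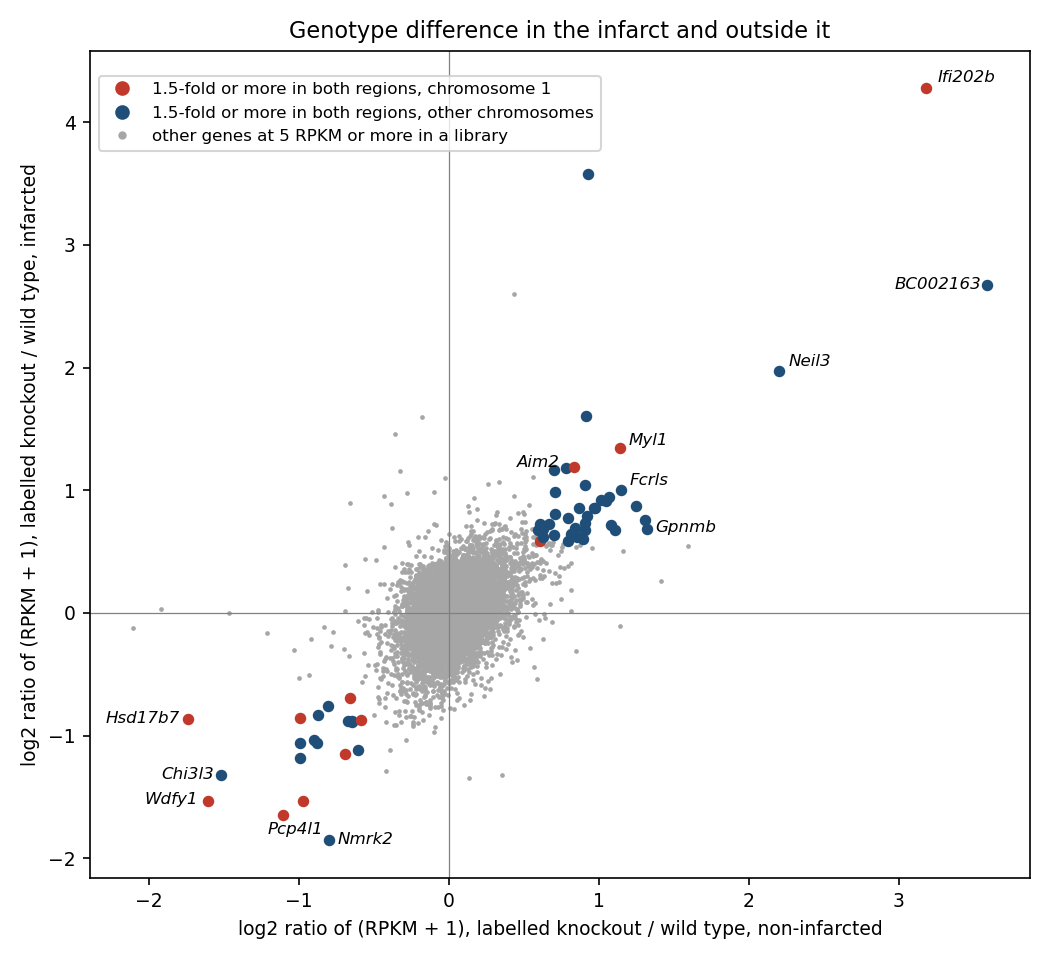
Log2 ratio of (RPKM + 1) between the library labelled knockout and wild type in infarcted tissue (vertical axis) against the same ratio in non-infarcted tissue (horizontal axis), 1 point per gene at 5 RPKM or more in at least 1 library. Coloured points differ at least 1.5-fold in the same direction in both regions, red on chromosome 1 and blue elsewhere. Ifi202b lies at 4.28 and 3.18 and Wdfy1 at -1.53 and -1.61 in infarcted and non-infarcted tissue.

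The third question was the same genotype difference outside the infarct. BC002163 was 53.2-fold higher (14.3 to 445) in the non-infarcted library labelled knockout, Ifi202b 81.0-fold higher (27.4 to 395) and Neil3 6.57-fold higher (5.02 to 8.74). Sprr1a, a stress-induced protein of cardiomyocytes, was at 608 against 200 RPKM, 3.04-fold higher (2.90 to 3.18). The macrophage glycoprotein Gpnmb (2.64-fold, 2.40 to 2.91), Serpinb1a, an inhibitor of neutrophil elastase (2.60-fold, 2.30 to 2.95), Pdk4, the kinase that shuts off pyruvate dehydrogenase (2.40-fold, 2.31 to 2.5), the sodium channel subunit Scn4b (2.69-fold, 2.25 to 3.23), Fcrls (2.30-fold, 2.05 to 2.58) and Ces1d (2.48-fold, 2.02 to 3.06) were also higher. Among lower genes were the atrial Myl7 (4.61-fold, 3.67 to 5.84), Myl4 (3.94-fold, 3.38 to 4.62) and Sln (3.56-fold, 2.05 to 6.48). Hsd17b7, an enzyme of cholesterol synthesis, was 6.12-fold lower (4.60 to 8.29), Wdfy1 3.54-fold (3.09 to 4.06), Chi3l3 3.48-fold (2.65 to 4.63), Prg4, which codes for lubricin, 2.36-fold (2.23 to 2.5) and the immediate early factor Egr1 2.06-fold (1.89 to 2.24), followed by Pcp4l1 and Pirt.

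At 2-fold, 31 genes were higher and 23 lower among 12226 compared, of which 9 and 8 were ribosomal or small noncoding RNA genes. Antigen presentation genes had a median of 0.45 and monocyte and macrophage genes one of 0.41, both at percentile 100. H2-Aa was 2.06-fold (1.83 to 2.33), Cd74 1.89-fold (1.77 to 2.02) and the lysozyme Lyz2 1.81-fold (1.74 to 1.88) higher. Extracellular matrix genes were at 0.18 (percentile 100) and cell cycle genes at 0.15 (percentile 99.98), with Col1a1 1.47-fold higher (1.45 to 1.49). Fibroblast genes, at 0.09 (percentile 97.6), lost their call under 8 settings. Cytokines and chemokines were lower, at -0.31 (percentile 0), with Ccl7 1.98-fold (1.59 to 2.47) and Ccl2 1.76-fold (1.49 to 2.09) lower. Immediate early genes were at -0.32 (percentile 0) and cardiomyocyte contractile genes at -0.08 (percentile 0.21), the latter within random lists once the 20 highest genes were left out. The atrial list was at -1.47 (percentile 0), with 3 of 5 genes at least 2-fold lower. The skeletal muscle median of 0.74 (percentile 99.99) rested on 3 genes and turned to -0.01 with no filter on expression. Calcium handling (-0.03), cardiac stress (-0.04), fatty acid oxidation (0.07), glycolysis (-0.04), neutrophil (-0.07), interferon response (-0.00), matrix protease (0.06), p53 target (0.02), DNA methylation (0.11), endothelial (-0.05), smooth muscle (-0.05), heat shock (-0.01), erythrocyte (-0.13), adipocyte (-0.03), mesothelial (0.12) and sex-linked (-0.01) genes lay within random lists. So did oxidative phosphorylation (0.00) and base excision repair genes (0.00), whose signs turned under other scalings. Only 1 lymphocyte gene could be compared. In all, 10 of 28 lists stood apart, where lists of random genes would give 1.40, which again leaves out differences between mice or dissections.

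The genotype difference was partly shared between the regions. Of 11974 genes compared in both, 22 and 25 were at least 2-fold higher in the libraries labelled knockout in infarcted and non-infarcted tissue, and 7 were shared against 0.0459 for independent lists: Ifi202b, BC002163, Neil3, Myl1, Fcrls, Rnu2-10 and Snora64. Of the 21 and 15 lower genes 6 were shared against 0.0263, among them Wdfy1, Chi3l3, Pcp4l1, Pydc3 and Snord16a. Of these, Rnu2-10, Snora64, Pydc3 and Snord16a lie outside the rule for named genes and were named after their values were seen. Rnu2-10, Snora64 and Snord16a rest on few reads: 1 and 3, 1 and 1, and 4 and 6 in wild-type non-infarcted and infarcted tissue. In the libraries labelled knockout they had 5 and 17, 5 and 6, and 0 and 1. Without ribosomal and small noncoding RNA genes, 5 higher and 5 lower genes were shared. In opposite directions, 1 gene was at least 2-fold apart, higher in infarcted and lower in non-infarcted tissue. The Pearson correlation across genes was 0.419 and the Spearman correlation 0.305. The labels do not say whether both libraries of a genotype came from the same mice.

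The last question was whether the response to infarction differed between genotypes. This difference was taken as the infarcted to non-infarcted log2 ratio of (RPKM + 1) in the libraries labelled knockout minus that in wild type. Because of the added 1 RPKM, it does not equal the difference between the RPKM folds printed beside it. The chemokine genes Cxcl5 and Ppbp had the larger ratio in the libraries labelled knockout. Cxcl5 was 21.6-fold (15.2 to 31.7) higher in infarcted tissue there and 5.59-fold (4.31 to 7.34) in wild type, a log2 difference of 1.56, and Ppbp 16.9-fold (11.9 to 24.8) and 5.64-fold (4.2 to 7.71), a difference of 1.38. The atrial genes Myl7, Myl4 and Sln differed by 1.98, 1.95 and 1.47, following their higher level in wild-type non-infarcted tissue. In both infarcted libraries Sln had no reads and Myl7 lay below 1 RPKM. Their values thus largely restate the difference between the non-infarcted libraries. Among genes with the smaller ratio in the libraries labelled knockout were Ces1d (-1.25), the ribosomal protein of striated muscle Rpl3l (-1.13), Nmrk2 (-1.06), Sprr1a (-1.05) and the muscle fructose bisphosphatase Fbp2. At 2-fold, 38 genes differed upward and 29 downward among 12716 compared, and 22 and 15 of them were ribosomal or small noncoding RNA genes, without which the counts were 17 and 13.

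Muscle and energy lists had the more negative response in the libraries labelled knockout, with median differences of -0.48 for cardiomyocyte contractile, -0.30 for calcium handling, -0.37 for oxidative phosphorylation, -0.40 for fatty acid oxidation and -0.27 for glycolysis and hypoxia genes. Cytokines and chemokines (0.37), neutrophil (0.32), cell cycle (0.27), extracellular matrix (0.21) and fibroblast genes (0.21) had the more positive response. Each of these medians lay outside the central 95% of random lists, as did the atrial list (1.47), which mirrors its -1.47 between the non-infarcted libraries. Skeletal muscle (0.29), smooth muscle (0.20) and immediate early genes (0.12) did so too, but each lost its call under at least 1 setting. Against wild type, cytokine and neutrophil genes of the library labelled knockout lay within random lists in infarcted tissue (0.09 and 0.14). In non-infarcted tissue they were at -0.31 (percentile 0) and -0.07, so the larger part of the cytokine difference lay between the non-infarcted libraries. With the filter at 5 RPKM, cytokine genes stood apart in infarcted tissue too (0.177), and neutrophil genes in non-infarcted tissue (-0.329). Monocyte and macrophage (-0.08), antigen presentation (-0.09), interferon response (0.07), base excision repair (0.07) and endothelial genes (-0.06) lay within random lists, as did cardiac stress (-0.26), protease (0.08), lymphocyte (-0.11), p53 target (-0.06), DNA methylation (0.03), heat shock (-0.02), erythrocyte (-0.17), adipocyte (-0.08), mesothelial (-0.13) and sex-linked genes (0.23). In all, 14 of 29 lists stood apart, where lists of random genes would give 1.45. With 1 library per group, the difference of infarct responses cannot be set against the spread between mice.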

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

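The tests in this part, on cardiomyocyte share, RNA content and single libraries, were chosen after the result was seen. List medians of the library labelled knockout against wild type were singled out where the regions had opposite signs and both the median in at least 1 region and the difference of infarct responses stood apart from random lists. Oxidative phosphorylation genes were lower in infarcted tissue (-0.311) and not in non-infarcted tissue (0.00424, a sign that turned under TMM scaling and without the 20 highest genes), and fatty acid oxidation genes were at -0.274 and 0.0746. Inflammatory cytokines and chemokines were at 0.0871 in infarcted (18 genes) and -0.312 in non-infarcted tissue (15 genes). Atrial genes were at 0.0316 over 3 compared genes and -1.47 over 5, since Myl7 and Sln lay below the filter in infarcted tissue. With no filter the infarcted atrial median was -0.103, so its opposite sign rests on which genes were compared. With 1 library per group, the difference between the regions was not tested, and no biological explanation was tested for the cytokine and atrial lists.

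The lower energy lists went with a wider pattern in the infarcted library labelled knockout, in which matrix and cell cycle lists were higher and cardiomyocyte lists lower. A smaller share of cardiomyocytes alone would raise the markers of every other cell type alike. The extracellular matrix and endothelial medians lay 0.6006 apart on the log2 scale. The bootstrap interval of 0.327 to 0.757 resampled member genes within 1 pair of libraries, which are not replicates. If the shares of other cell types changed as well, the same gap could arise, so it cannot exclude a difference in cell composition. Ribosomal and small noncoding RNA content would scale all other genes by 1 factor, which the same gap argues against. The lists of this pattern already moved in opposite directions, which 1 factor cannot produce, so the gap adds no separate support. Differences between individual mice or dissections cannot be told apart from an effect of genotype, with 1 library per group. Genotype effects on repair tissue, a more advanced repair in the sampled piece or a different cell mix there may therefore each underlie the pattern.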

How the results depend on the processing

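Leaving out ribosomal and small noncoding RNA genes, and leaving out chromosome 1, were chosen after seeing the data, and the other alternatives before the data were examined. Of 134 counts under alternatives, 70 stayed within 1.5 times the reported count and 64 did not. Counts are given as higher and lower in turn, for the libraries labelled knockout against wild type in infarcted tissue, the same in non-infarcted tissue, and the difference of infarct responses.

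With a pseudocount of 0.1 RPKM these counts were 70 and 71, 70 and 48, and 99 and 100. Genes higher in infarcted tissue numbered 1262 in wild type and 1578 in the libraries labelled knockout, shared higher genes numbered 990, and genes shared between regions 16 higher and 13 lower. With scaled counts (CPM) and 0.5 reads added they were 81 and 80, 80 and 53, and 124 and 119, genes higher in infarcted tissue 1324 and 1625, shared higher genes 1038, and genes shared between regions 16 and 14. Both settings add less to low values, so more genes with few reads pass by construction.

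With a filter at 5 RPKM the counts were 18 and 14, 16 and 9, and 19 and 9, with 3 lower genes shared between regions, since fewer genes were compared. Median-ratio scaling gave 460 higher and 762 lower genes in infarcted wild-type tissue, 552 higher in the libraries labelled knockout, and 348 higher and 701 lower shared genes. TMM scaling gave 458 and 770, 544, and 345 and 707. The shift of the median of all genes under these scalings moves genes from higher to lower by construction.

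At a threshold of 1.5-fold the counts were 188 and 193, 139 and 75, and 142 and 197, with 2698 and 1196 genes in infarcted against non-infarcted wild-type tissue and 3146 and 1557 in the libraries labelled knockout. At 4-fold they were 4 and 0, 4 and 1, and 3 and 2, with 37 and 22 genes in wild type and 64 and 71 in the libraries labelled knockout. Without ribosomal and small noncoding RNA genes the counts were 13 and 19 for infarcted tissue and 17 and 13 for the difference of infarct responses. Without chromosome 1, 2 lower genes were shared between regions. No filter, and leaving out the 20 highest genes, moved none of the counts beyond 1.5 times.

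Of the list medians, 1365 kept their side of the random range, and 49 of these, all inside it, changed sign. Another 34 came to stand apart, 31 ceased to, and 1 that stood apart reversed: skeletal muscle genes in non-infarcted tissue, from 0.74 to -0.0055 with no filter. Calls ended for infarcted against non-infarcted tissue in the DNA methylation list (libraries labelled knockout, 8 settings, 0.396 to 0.654), the immediate early list (libraries labelled knockout, 6 settings, 0.346 to 0.593) and the adipocyte list (wild type, at -0.902 with pseudocount 0.1, -0.435 with the 5 RPKM filter and -0.906 as CPM). In non-infarcted tissue they ended for fibroblast genes (8 settings, 0.0751 to 0.0976) and for cardiomyocyte genes with the 20 highest genes left out (-0.0898). For the difference of infarct responses they ended for skeletal muscle genes (0.0743 with no filter, 0.340 at 5 RPKM, 0.286 as a mean), smooth muscle genes (0.0667 as a mean) and immediate early genes (0.116 with no filter). The cause was not tested.

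Calls were gained for infarcted against non-infarcted tissue in the adipocyte list (libraries labelled knockout, 5 settings, -1.32 to -0.151) and the DNA methylation list (wild type, as CPM and as a mean). In 1 setting each they were gained for glycolysis and interferon genes (wild type, as a mean), sex-linked genes (wild type, no filter), and lymphocyte, erythrocyte and mesothelial genes (libraries labelled knockout, no filter). Against wild type, calls were gained in infarcted tissue for cytokines and chemokines (0.177 at 5 RPKM), erythrocyte genes (-0.197 with no filter, -0.255 as a mean) and sex-linked genes (0.218 with no filter). In non-infarcted tissue they were gained in 3 settings each for neutrophil (-0.329 to -0.0945), erythrocyte (-0.144 to -0.129) and fatty acid oxidation genes (0.0746 to 0.0764), and in 1 each for calcium handling (5 RPKM), cardiac stress and mesothelial genes (as a mean). For the difference of infarct responses they were gained for cardiac stress (3 settings, -0.344 to -0.260), matrix protease (as a mean) and mesothelial genes (no filter).

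Of the values of the ranked genes and Neil3, 540 moved by less than their counting interval and 64 by more. None with a log2 ratio of 1 or more in size changed sign, and smaller values were not checked for sign. Genes named only as list members were not checked. The planned sum over entries of 1 symbol was not run, since 0 symbols occurred more than once, and 0 genes of the mitochondrial genome were listed. Depth limits genes with few reads, as 3 reads are an RPM of 0.165 to 0.210.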

Other observations

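Biological process terms from the deposited files were chosen after the ranking was seen, from the 8 at each end of 435 to 450 terms per comparison, and share some genes with the fixed lists. In infarcted against non-infarcted tissue, leukocyte chemotaxis genes had a median log2 ratio of 1.07 in wild type and 1.02 in the libraries labelled knockout, led by Cxcl3, Csf3r, Il1b and Ppbp. Defense response to bacterium was at 0.91 and 0.98. Regulation of angiogenesis was at 0.77 in wild type, with 17 of 41 genes at least 2-fold higher, among them Angptl4 and Angpt2. Phagocytosis was at 0.94 in the libraries labelled knockout, with 24 of 25 genes above 0 and the Fc receptors Fcgr2b and Fcgr1 among the leading genes. Aerobic respiration was at -0.99 and -1.28, led by the citrate cycle enzymes Idh2 and Mdh1.

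Against wild type, the infarcted library labelled knockout had lower medians, among 440 terms, for glycogen metabolism (-0.26, 5 of 16 genes above 0, with Gbe1 and Gys1 lower) and vasodilation (-0.24, 5 of 18 genes above 0, with Agtr1a lower and Hmox1 higher). In both terms 0 genes were 2-fold lower. Mitotic sister chromatid segregation was higher (0.27, 23 of 25 genes above 0), as were humoral immune response genes, which include the complement components C3 and C1qa (0.21), and nucleosome organization genes (0.17). In non-infarcted tissue, the immune response term was at 0.23, with Trem2 and C1qc among the leading genes. The Y-linked Ddx3y lay between 14.5 and 17.3 RPKM in the 4 libraries.

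The tests on Neil3 and on gene positions were chosen after the results were seen. More Neil3 reads were found in the libraries labelled knockout. If the genotype labels had been exchanged, these libraries would hold an intact transcript, but Neil3 coverage stood at the 2.736 percentile of like genes at most. In the wild-type libraries it stood at the 15.59 percentile at least. This is consistent with a transcript in the libraries labelled knockout that lacks part of the gene, and the labels do not name the deleted part.

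Of 83 genes at least 1.5-fold apart in the same direction in both regions, 12 lay in 1 run of 100 neighbouring expressed genes on chromosome 1, where random sets had 3 to 6 and at most 7. Small noncoding RNA genes with few reads were kept among the 83, such as Snora52 with at most 2 reads in a library. The run of 12 held no such gene. Among the 12 were Ifi202b, Aim2 and AI607873, higher in the libraries labelled knockout, and Pcp4l1, Pydc3, Dusp23, Slamf7, Mnda, Hsd17b7 and Pyhin1, lower there. Of the p200 and Slam family genes in the run, 3 were higher and 4 lower in both regions, so they did not all move the same way. Mixed directions cannot exclude a cause within these families, since related genes need not move alike. Without these families 5 genes were left in the run, within the range of random sets. The fullest run was then 6 genes on chromosome 17, above a bound of 5 but below the highest random number of 7. It held the antigen presentation genes H2-Aa, H2-Ab1, H2-Eb1 and H2-DMa and also Angptl4, all higher. Its other member was Mir877, lower from at most 2 reads in a library. The antigen presentation genes alone stay below that bound, so this run does not show that a cluster of related genes can pass it. A chromosome segment that differs between the mouse lines may underlie the run of 12, since Ifi202b expression is known to differ between inbred strains. Neil3 itself lies on chromosome 8, where 0 of its 40 expressed neighbours, 20 on each side, were among the 83 genes. This lies inside the bound of 2 for windows of 40 genes, so it does not decide the question.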
